A study of Mus musculus with 25 samples.

How the data were processed

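Total RNA from cultured mouse cells and from embryonic germ cells was labelled and read on 25 Affymetrix arrays of 45101 probe sets, of a type that reads transcripts near their 3′ end. The deposited values are log2 RMA signals: per the submitters' processing notes, Affymetrix Expression Console 1.3.0.187 was used with RMA, which corrects the background, equalises the distribution of signal across arrays and combines the probes of each probe set. The labels state the same labelling kit for all arrays. Whether all 25 arrays were normalized together is not stated. Equal distributions across arrays mean that a rise of many transcripts on an array lowers the others, so that changes are relative. The deposited table and the values listed per sample were compared, and all 25 columns were found in both with the same values. Of the deposited columns, 21 carry the sample's name. The other 4, of the E12.5 PGCs, carry no replicate number and were kept as a group, told apart by run only, with a number in the column names read as the run.

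Of the probe sets, 64 were controls, 38011 were named for 1 gene, 1280 for several and 5746 for none. Those named for 1 gene covered 20677 genes, and each gene was represented by the probe set with the highest mean over all arrays. A gene was tested if that probe set lay above its array's median on at least 2 arrays, which left 14364 genes. Of the genes fixed in advance to be reported, Nanos3 had no probe set of its own and Hoxb1 lay below this filter. Coordinates are those of the deposited annotation on build NCBIM37.

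A single linear model with a mean for each of the 7 groups was fitted to all 25 arrays with limma 3.58.1 in R 4.3.3 (files read with version 1.17.8 of data.table), with 18 residual and 3.5 prior degrees of freedom. Because all groups shared the estimate of spread, a group of 1 or 2 arrays could be tested, on the assumption that it varied like the others. Cell types pooled over ESC and iPSC origin were means over their arrays. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, within each of 10 comparisons. A gene was called at an adjusted p under 0.05, and the counts given are of calls of at least 2-fold. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 38 lists of a comparison, and beside each list stands the number of its members called over all genes and, where it differs, adjusted over the list alone. Over all comparisons 76 of 380 list tests passed, and 10 of these, named in the results, kept the call with an estimated correlation. Some lists share members, so that these calls are not all independent. The alternative test fry asks whether the genes of a list move on balance 1 way, or with its mixed form in either direction, without comparing them with other genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used to read the files and draw the figures.

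The comparisons, tests, filter, gene lists, alternatives and the rule for named genes were chosen before the data were examined. For each comparison of cell types the rule takes the 10 genes with the largest rise and the 10 with the largest fall among calls whose groups did not overlap on any array, leaving out names that are only a clone or model number, the genes fixed in advance, and up to 4 called members of each list. For the comparisons of origin it takes all calls of 2-fold or more if 10 or fewer, otherwise the 5 with the largest change each way, and the members of the Dlk1-Dio3 list. The text gives part of these, and some genes that the rule takes are not reported here. Y-linked and X inactivation transcripts are not reported for single samples.

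Clone numbers recur across stem cells, EpiLCs and PGCLCs, so the cell line was tried as a block in the comparisons within cell lines, as a fixed and as a random effect. Arrays of the same line hardly resembled each other beyond their group: 18 pairs of arrays of the same line had a mean correlation of 0.038 across genes (6 above 0.1), against −0.011 for 62 pairs of different lines, and the random effect gave a correlation of 0.0077. Other alternatives changed the probe set per gene, the filter, the scaling (each array centred on its median, or quantile normalization repeated), the weights, the moderation of the spread, the threshold, the arrays in the fit and the weighting of origins, and left out each array in turn. After the data were seen, the PGC comparisons were repeated with only the PGC array that shares the run of the cultured cells and with only the other 3, and all comparisons with PGCLCs without the PGCLC arrays from ESC clone 1 and iPSC clone 3.

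The method was tested on simulated data of the size of this series, with 14364 genes, some of them changed by known amounts in each comparison. The noise had 1 spread per gene, estimated from these data and the same in all groups. It was drawn independently for each gene and array. The real groups differed in spread, and neither runs, cell lines nor correlation between genes were simulated. The rates below therefore describe such noise and may not hold for these data. Of those changed 2-fold, 74.6% were recovered between EpiLCs and stem cells, 62.7% between PGCLCs and EpiLCs, 71.6% between PGCLCs and stem cells and 59.7% in both comparisons with PGCs. For the origin, 40.3% were recovered between iPSCs and ESCs, 26.9% in EpiLCs and 22.4% in PGCLCs, and 3% and 6% as a difference of the first and the second step. Of those changed 4-fold, 92.4% to 97% were recovered between cell types, 90.9%, 71.2% and 74.2% between origins, and 62.1% and 48.5% as a difference of a step. None had the wrong sign, and 1 to 10 unchanged genes were called per comparison. A list raised on purpose in EpiLCs was called by camera against stem cells, with 0 of the other lists.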

Results

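RNA abundance was measured on 25 arrays along a mouse culture protocol that turns pluripotent stem cells into primordial germ cell-like cells (PGCLCs), the cultured counterpart of the precursors of eggs and sperm. The stem cells were 3 embryonic stem cell (ESC) clones and 6 induced pluripotent stem cell (iPSC) clones, iPSCs being somatic cells reset to a stem cell state. Epiblast-like cells (EpiLCs), the intermediate of the protocol, were profiled from 2 ESC and 4 iPSC clones. PGCLCs from the same 6 clones came from embryoid bodies after 6 days of induction. Primordial germ cells (PGCs) sorted from the genital ridges of mouse embryos (E12.5) filled 4 further arrays. PGCLCs and PGCs were sorted on the surface markers SSEA1 and CD61, except that the label of the PGCLC sample from iPSC clone 4 gives no sort. By the labels, the embryos were C57BL/6 of unknown sex, while all cultured lines were male and of mixed C57BL/6 and 129/Sv background. Strain, sex and embryo against culture thus go together with the PGC comparisons. The labelled sex was not tested. Y-linked transcripts had a list mean of 5.43 ± 0.79 (SD, n = 9) in stem cells and 7.12 ± 0.14 (SD, n = 4) in PGCs. Each array gives 1 value per transcript, and the number of arrays limits the precision. A number in the deposited column names was read as the code of a run, but the labels do not say what it means. Read so, 20 of the 21 cultured-cell arrays and 1 PGC array share 1 run. The array of iPSC clone 2 has a code of its own, and the other 3 PGC arrays share the last. The first principal component carried 41.9% of the variance of the 14364 tested genes. On it the 3 PGC arrays of the last run lay apart from all other arrays, and the PGC array of the cultured cells' run lay near the PGCLCs.

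**Figure D1:**
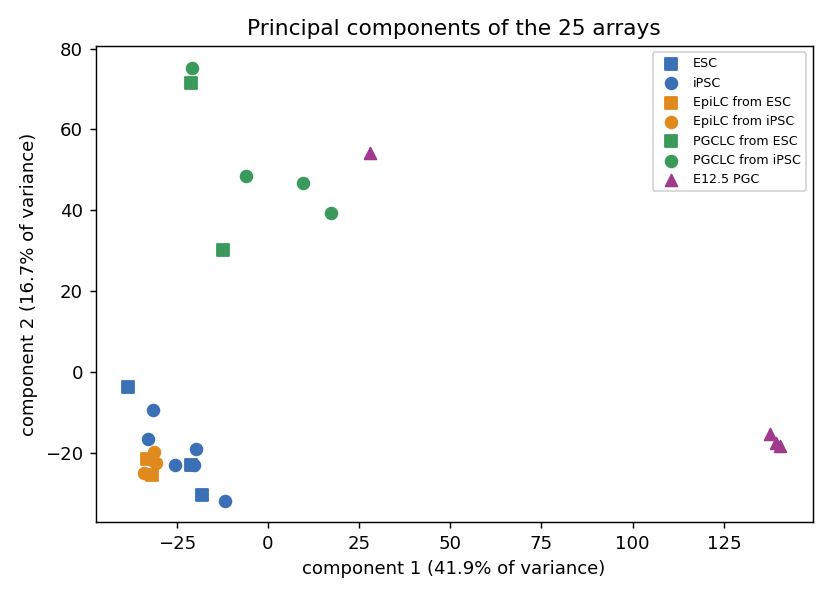
Each point is 1 of the 25 arrays, placed by its scores on the first and second principal components of the 14364 tested genes (41.9% and 16.7% of the variance, in log2 units). Colours and shapes give the cell type and the origin, and 3 of the 4 E12.5 PGC arrays lie apart from the fourth.

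The step from stem cells to EpiLCs asks how the cells change as they leave the naive state of the early embryo. Transcripts of naive pluripotency fell together: 19 of the 20 measured members of that list fell, and all 20 did when adjusted over the list alone, with a list median of −3.27 (log2). The nuclear receptor Nr0b1 fell from 11.06 ± 0.51 (SD, n = 9) to 5.23 ± 0.65 (SD, n = 6), a 56.6-fold change (limma, adjusted p = 1.12e-11). The naive transcription factors Esrrb (log2 change −4.19, adjusted p = 3.61e-11), Klf4 (−3.73), Klf2 (17.7-fold lower) and Zfp42 (−3.37) fell as well. Prdm14, a regulator of both naive pluripotency and germ cell fate, fell 22.1-fold, from 8.13 ± 0.62 (SD, n = 9) to 3.67 ± 0.18 (SD, n = 6). Of the core factors, Nanog fell by 0.55 (adjusted p = 0.00125) and Sox2 by 1.49 (4.25e-06). The value for Pou5f1, which encodes Oct4, was −0.24 (adjusted p = 0.384), and it passed the test with the cell line as a block (−0.43, adjusted p = 0.0377) and with array weights (−0.36, 0.00484). Fgf5, the classical marker of the formative and primed epiblast, rose from 5.65 ± 1.10 (SD, n = 9) to 9.21 ± 0.44 (SD, n = 6), 11.8-fold (adjusted p = 4.44e-06). Its probe set lies on chromosome 5 at 98705414 to 98706051 (build NCBIM37).

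Among the other lists of this step, 12 of 18 primed epiblast transcripts rose and 1 fell (13 and 1 adjusted over the list alone). The signalling ligand Wnt3 rose by 2.69 (adjusted p = 8.25e-05) and the mesoderm factor T by 1.56 (0.00532). Their list, of mesoderm and primitive streak, rose for 5 of 20 and fell for 2 (5 and 3 adjusted over the list alone), and did not pass by camera (adjusted p = 0.827). Genes of cholesterol synthesis and uptake rose almost as a block: 19 of 20 rose (20 adjusted over the list alone), among them Fdps, the farnesyl diphosphate synthase (1.77, adjusted p = 5.47e-05). Early germ cell transcripts fell, 11 of 19 (12 adjusted over the list alone), including Tfap2c (−2.17) and Ifitm1 (−3.51). Of 15 general pluripotency transcripts 6 fell and 1, Lin28a (0.55), rose. The call of Lin28a was lost with each array centred on its median (adjusted p = 0.0701) and with the origins weighted equally (0.0685). Tcl1, a cofactor of the kinase Akt (32.7-fold), the adhesion gene Jam2 (35.9-fold), the signalling ligands Bmp4 (19.8-fold) and Inhbb (18.9-fold) were lower in EpiLCs. So were the BMP target Id1 (−2.32), the DNA demethylase Tet2 (−3.10) and the DNA methyltransferase cofactor Dnmt3l (−2.37, adjusted p = 4.16e-08). The de novo methyltransferases Dnmt3a (0.13, adjusted p = 0.656) and Dnmt3b (0.35, 0.441) did not pass the test on their brightest probe set. With the mean of their probe sets they did, at 0.79 (adjusted p = 3.58e-05) and 0.59 (0.0331). Dnmt3b also passed with array weights (0.40, 0.0268) and with only the arrays compared in the fit (0.35, 0.0211).

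In all, 1055 genes changed at least 2-fold between EpiLCs and stem cells, 540 higher and 515 lower (limma, adjusted p under 0.05). By camera, which compares a list with all other genes, naive pluripotency (adjusted p = 3.46e-33), cholesterol synthesis (4.34e-19), early germ cell (3.13e-10), primed epiblast (5.6e-07) and general pluripotency (0.00206) passed. With an estimated correlation the first 3 kept their calls (adjusted p = 0.000476, 0.0282 and 0.0282), and primed epiblast (adjusted p = 0.0542) and general pluripotency (0.565) did not.

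The step from EpiLCs to PGCLCs asks which genes come on as germ cell fate is induced. The germ cell regulators rose together: 14 of 19 early germ cell transcripts were higher and none lower (16 adjusted over the list alone), with a list median of 2.78. Prdm14 went from 3.67 ± 0.18 (SD, n = 6) to 9.74 ± 1.07 (SD, n = 6), a 67-fold rise (limma, adjusted p = 3.1e-10; chromosome 1, 13103508 to 13104268, NCBIM37). The other members of the PGC specification trio, Prdm1 (2.94, adjusted p = 0.000137) and Tfap2c (3.28, 1.3e-09), rose with it. So did Dppa3 (2.04, 0.000515), the receptor Kit (2.98) and Itgb3 (3.36, 2.17e-08), which encodes the CD61 used in the sort and so was selected for. On the PGCLC array from iPSC clone 3, Prdm1 (6.71) and Dppa3 (9.5) stayed within the range of the EpiLC arrays (6.18 to 6.84 and 8.55 to 10.02). Tfap2c (12.37) lay above that range there (8.35 to 9.76). Naive pluripotency came back, 18 of 20 members higher and none lower (18 and 1 adjusted over the list alone), among them Esrrb (4.33), Klf4 (2.98) and Zfp42 (2.62). Of the general factors Sox2 (1.43) and Nanog (0.69) rose, and Pou5f1 did not pass (−0.05, adjusted p = 0.894).

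BMP targets also rose between EpiLCs and PGCLCs, 9 of 12 higher (10 adjusted over the list alone), in a culture whose induction protocol uses BMP. Id3 rose by 3.45 (adjusted p = 5.49e-12) and Msx2 by 4.34. The T-box factor Tbx3, a member of the naive pluripotency list and not of this one, rose 35.5-fold. Trophoblast transcripts were higher for 7 of 13 (8 adjusted over the list alone), with Cdx2 (3.35) and Plac1 (3.41). Paternally expressed imprinted genes were higher for 8 of 25 with 1 lower (10 and 1 adjusted over the list alone), with Igf2 (4.38), Dlk1 (3.56) and Peg3 (2.56). Of the X-linked Rhox cluster, Rhox9 rose 39.4-fold and Rhox6 23.6-fold, and Tac2, a tachykinin precursor, rose 62.4-fold to 10.61 ± 2.45 (SD, n = 6). Of 22 endoderm transcripts 4 rose and 1 fell (3 and 1 adjusted over the list alone), with Afp (3.36) and Ttr (3.18) higher on every PGCLC array than on any EpiLC array. Of 16 fibroblast transcripts 4 rose, among them the collagen Col1a1 (3.12, adjusted p = 0.0119), and 2 fell. Neither list passed by camera (adjusted p = 0.482 and 0.272). The call of Col1a1 was lost without the PGCLC arrays from ESC clone 1 and iPSC clone 3 (2.25, 0.097).

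Cholesterol synthesis and primed epiblast transcripts, which had risen in EpiLCs, fell again. Cholesterol synthesis fell for 19 of 20 members (20 adjusted over the list alone; Fdps −2.11). Primed epiblast fell for 15 of 18 with 1 higher, with Fgf5 16.5-fold lower, Pou3f1 at −3.26 and Otx2 at −2.92. Glycolysis, which lay at a list mean of 11.69 in stem cells and 11.72 in EpiLCs, fell for 16 of 20 with 2 higher, with the phosphofructokinase Pfkl at −2.14 and the lactate exporter Slc16a3 12.3-fold lower. The hexokinase Hk1 moved the other way (1.82), except on its most variable probe set (0.89, adjusted p = 0.0942). The methyltransferases Dnmt3b (−2.23) and Dnmt3a (−1.54), the neural genes Sox1 (−2.32) and Nes (−2.19) were lower in PGCLCs than in EpiLCs. So were Mael (−2.43), Sycp3 (−1.50) and Ddx4 (−0.96), which act later in germ cells or in meiosis.

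Between EpiLCs and PGCLCs 1834 genes changed at least 2-fold, 982 higher and 852 lower. Camera gave adjusted p = 6.98e-18 for naive pluripotency, 1.44e-14 for cholesterol synthesis, 1.51e-14 for early germ cell, 2.16e-09 for BMP targets and 2.3e-08 for primed epiblast. These kept their calls with an estimated correlation (adjusted p from 0.00866 to 0.0388). Glycolysis (2.84e-06), trophoblast (0.000331) and paternally expressed imprinted genes (0.0391) lost theirs, at adjusted p = 0.0644, 0.106 and 0.648 with an estimated correlation. The imprinted list also lost it with the cell line as a block (adjusted p = 0.0602).

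**Figure D2:**
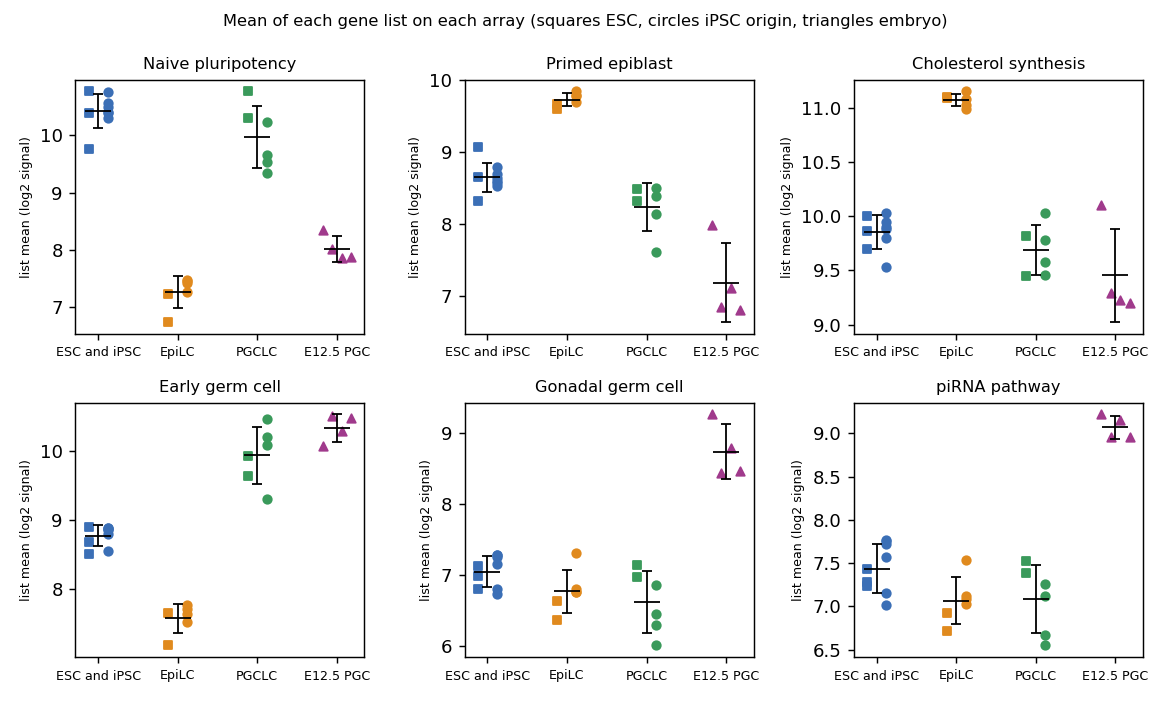
Mean log2 signal of 6 of the gene lists on each array, by cell type, with squares for ESC origin, circles for iPSC origin, triangles for E12.5 PGCs, and the mean and SD of each cell type in black. Naive pluripotency and early germ cell transcripts dip in EpiLCs and return in PGCLCs, cholesterol synthesis does the opposite, and gonadal germ cell transcripts are highest in PGCs.

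Over both steps, PGCLCs against stem cells shows what differed at the end. Naive pluripotency lay at a list median of −0.45, with 6 of 20 members lower and the camera test not passed (adjusted p = 0.0771). Nanog (0.14, adjusted p = 0.395), Sox2 (−0.06, 0.840) and Esrrb (0.14, 0.688) did not pass. Early germ cell transcripts were higher for 8 of 19 and lower for 1 (9 and 2 adjusted over the list alone). Higher were Prdm1 (2.11), Kit (2.02), Prdm14 (1.60), Tfap2c (1.12) and Itgb3 (3.10), the sorted marker. Dppa3 (0.92, adjusted p = 0.0658) passed with array weights (1.27, 0.00119), without the PGCLC array from iPSC clone 3 (1.34, 0.000144), without this and that from ESC clone 1 (1.62, 4.98e-05), and without the stem cells of ESC clone 1 (1.05, 0.0438). BMP targets rose for 8 of 12 (Msx2 16.6-fold), trophoblast for 9 of 13 (10 adjusted over the list alone; Plac1 3.60, Cdx2 3.25, Gata2 2.78). Of 25 paternally expressed imprinted genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), with Igf2 26.2-fold higher. H19 (3.88) and Igf2r (1.73), imprinted genes expressed from the maternal copy, rose too.

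Glycolysis stayed lower in PGCLCs than in stem cells, for 13 of 20 with 1 higher (15 and 1 adjusted over the list alone; Slc16a3 −2.69, Pfkl −2.11). The DNA methylation machinery was lower at Dnmt3l (8.12-fold), Dnmt3b (−1.87) and Dnmt3a (−1.41). The list of methylation writers as a whole, with 4 higher and 4 lower of 14 (4 and 5 adjusted over the list alone), did not pass (adjusted p = 0.2). Cell cycle inhibitors rose for 7 of 15 (8 adjusted over the list alone; Cdkn1a, which encodes p21, 1.77), and 6 of 25 cell cycle genes fell, with Plk1 at −0.81. Immediate early genes that respond to tissue dissociation rose in 7 of 18 cases and fell in 1, with Fos 26-fold and Jun (2.88) higher. Meiosis fell for 6 of 20 with 2 higher (7 and 2 adjusted over the list alone; Sycp1 −1.57) and gonadal germ cell transcripts for 7 of 30 with 2 higher. Mael (−2.57) and Ddx4 (−1.02) were lower, and Dazl, an RNA-binding germ cell factor, was higher (1.43), except on its most variable probe set (0.57, adjusted p = 0.241). Mesoderm and primitive streak genes rose for 7 of 20 with 1 lower, fibroblast genes for 5 of 16 with 1 lower (7 and 1 adjusted over the list alone; Col1a1 3.89) and retinoic acid targets for 5 of 11. The fibroblast mean was 9.11 and 9.23 in the PGCLCs of ESC clone 1 and iPSC clone 3, 6.77 to 7.89 in the other 4, and 7.03 ± 0.24 (SD, n = 9) in stem cells. General pluripotency fell for 6 of 15 (8 adjusted over the list alone; Tdgf1 −1.09), primed epiblast for 7 of 18 with 1 higher and histone methylation genes for 8 of 20 with 2 higher.

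Between PGCLCs and stem cells 1402 genes changed at least 2-fold, 858 higher and 544 lower (limma). By camera 16 lists passed, from adjusted p = 4.26e-07 for BMP targets and glycolysis to 0.0475 for histone methylation and the cell cycle. None kept its call with an estimated correlation, the lowest adjusted p being 0.0779 for glycolysis, trophoblast and mesoderm. With the cell line as a block, primed epiblast (adjusted p = 0.0611), retinoic acid targets (0.0722) and histone methylation (0.0924) lost their calls.

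PGCLCs against E12.5 PGCs asks how far the cultured cells had come toward germ cells of the gonad. The late germ cell program was lower in PGCLCs: 27 of 30 gonadal germ cell transcripts were lower and none higher (27 and 1 adjusted over the list alone). The list median was −2.06 while the median of all genes was 0.272. Dazl, needed for germ cells to enter their sexual development, was at 8.26 ± 1.17 (SD, n = 6) in PGCLCs and 12.48 ± 0.36 (SD, n = 4) in PGCs, an 18.7-fold difference (limma, adjusted p = 3.59e-08; chromosome 17, 50418719 to 50432961, NCBIM37). It was −4.55 against the PGC array of the cultured cells' run and −4.12 against the 3 of the other run. Values given as within the runs, here and below, follow this order, each with the PGC arrays of 1 run. The cultured cells stay the same in both. The second value thus compares arrays of different runs, and both values are not independent. The helicase Ddx4 (−3.51, within the runs −4.33 and −3.24), the piRNA factor Mael (−3.74, −4.13 and −3.60) and the oocyte gene Khdc1a (24.6-fold lower, −5.41 and −4.36) were lower in both. The piRNA pathway, which silences transposons in germ cells, was lower for 15 of 19 with 1 higher (16 and 1 adjusted over the list alone). Meiosis was lower for 13 of 20 with 1 higher, with the synaptonemal complex gene Sycp3 (−2.22, −2.65 and −2.08), Smc1b (−3.70, −4.41 and −3.46) and Tex12 (−3.53, −4.15 and −3.32). Asz1 (−4.10, within the runs −1.40 and −5.01) and Tex19.1 (−4.16, −2.19 and −4.82), a piRNA and a transposon silencing gene, were lower by unequal amounts in the runs.

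The specification trio did not pass the test between PGCLCs and PGCs, with Prdm1 at −1.02 (adjusted p = 0.137), Prdm14 at 0.41 (0.451) and Tfap2c at 0.18 (0.596). Within the runs Prdm1 was −0.80 and −1.09, while Prdm14 (−0.79 and 0.81) and Tfap2c (1.05 and −0.11) changed sign between them, none past the threshold. Prdm1 passed with each array centred on its median (−1.62, adjusted p = 0.0205), with quantile normalization repeated (−1.39, 0.0481) and without the PGCLC array from iPSC clone 4 (−1.40, 0.0376). Prdm14 passed with array weights (1.22, 0.000309) and without the PGCLC arrays from ESC clone 1 and iPSC clone 3 (0.93, 0.0359). Higher in PGCLCs was Fgf4, a growth factor of the pluripotent epiblast, at 12.14 ± 1.04 (SD, n = 6) against 4.23 ± 0.27 (SD, n = 4), a 240-fold difference (adjusted p = 7.97e-14). Within the runs it was 7.73 and 7.96 (chromosome 7, 152050708 to 152051148, NCBIM37). Naive pluripotency was higher for 13 of 20 with 1 lower (13 and 2 adjusted over the list alone; median 1.65), with Esrrb (1.74, within the runs 1.62 and 1.79) and Zfp42 (1.95, 1.84 and 1.99). The methylation cofactor Dnmt3l (4.74, 4.61 and 4.78), Dnmt3b (3.65, 2.09 and 4.16) and the imprint guardian Zfp57 (4.97, 2.41 and 5.83) were higher. So were the imprinted genes Peg10 (4.77, 4.40 and 4.89) and Impact (3.69, 2.26 and 4.16) and 11 of 13 trophoblast transcripts (median 1.74). Uhrf1, which guides maintenance methylation, was higher at 2.82, from 3.48 in the other run, and did not pass in the cultured cells' run (0.85, adjusted p = 0.0949). Markers of macrophages, a cell type of the gonad that the sort could have let through, were lower in PGCLCs for 6 of 11 with 3 higher, with C1qb at −3.55 (−6.03 and −2.73).

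At least 2-fold differences between PGCLCs and PGCs numbered 4169, of which 3320 (79.6%) were higher in PGCLCs, but the direction depended on the PGC arrays and on the scaling. Against the PGC array of the cultured cells' run alone, 1589 genes passed and 41.3% were higher, and against the 3 of the other run 5514 passed and 80.3% were higher. The call was made in both runs with the same direction for 740 genes, 535 higher and 205 lower, and 86 were called in opposite directions. Both runs were set against the same PGCLC arrays, so these calls are not independent. Centring each array on its median moved the median of all genes from 0.272 to −0.333 and the split to 1531 higher and 2648 lower. The values above are thus to be read beside these medians. By camera, gonadal germ cell (adjusted p = 2.24e-20; 4.08e-22 and 9.07e-14 within the runs), the piRNA pathway (6.34e-12; 5.21e-10 and 7.52e-09), meiosis (9.46e-08; 1.36e-14 and 0.000275) and macrophages (0.0208; 2.26e-07 and 0.0297) passed in both runs. Naive pluripotency (0.0142; 1.43e-07 and 0.178), trophoblast (0.0274; 0.00596 and 0.178) and the list of 2-cell-like genes, 6 of 7 higher (0.0241; 0.000478 and 0.163) passed only in the cultured cells' run. With an estimated correlation gonadal germ cell and piRNA kept their calls (adjusted p = 0.0127 each), and the other 5 did not (adjusted p from 0.341 to 0.675). The gonadal germ cell list shares members with the piRNA list, such as Mael and Fkbp6, and with meiosis, such as Sycp1. Their calls are therefore not independent. The control probe sets for β-actin differed between these arrays. The β-actin signal at the 3′ end minus that at the 5′ end was −0.33, −0.41 and −0.24 on the 3 PGC arrays of the other run. It was 2.03 on the PGC array of the cultured cells' run, and 0.65 or more on every array of cultured cells. For GAPDH it was 1.11, 1.21 and 1.11 on the 3, 1.00 on the 1, and 0.49 to 1.92 on the arrays of cultured cells.

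**Figure D3:**
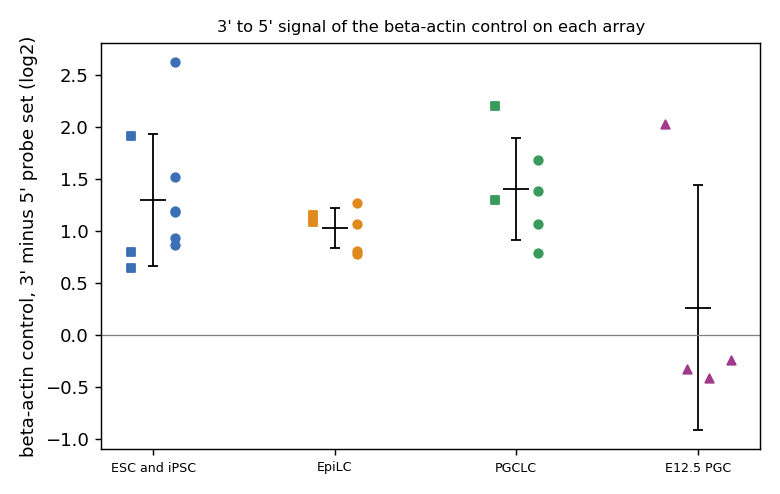
Signal of the β-actin control at the 3′ end minus that at the 5′ end, in log2 units, for each array by cell type, with the mean and SD in black (squares, ESC origin; circles, iPSC origin; triangles, PGCs). The 3 PGC arrays of the other run lie below 0, at −0.41 to −0.24, and all other arrays above it.

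E12.5 PGCs against stem cells gives the embryonic counterpart of the change made in culture. Gonadal germ cell transcripts were higher in PGCs for 25 of 30 with 1 lower (list median 1.48 beside −0.243 for all genes) and the piRNA pathway for 15 of 19 with 1 lower. Dazl was 50.3-fold higher (5.98 within the run of the cultured cells and 5.55 in the other), Rhox9 57.5-fold (4.89 and 6.16), Itgb3, the sorted marker, 53.8-fold (5.04 and 5.99), and Ddx4 rose by 2.49 (3.31 and 2.22). Early germ cell transcripts were higher for 10 of 19 with 3 lower, with Kit (3.29), Prdm1 (3.13) and Dppa3 (3.05). Meiosis was higher for 11 of 20 with 2 lower (11 and 3 adjusted over the list alone; Sycp3 1.18). Fgf4 was 526-fold lower (adjusted p = 5.34e-16; −8.87 and −9.10), Dnmt3l 216-fold lower (−7.63 and −7.80), Dnmt3b lower at −5.52 (−3.97 and −6.04) and Eras, a Ras gene of ESCs, 180-fold lower. Naive pluripotency was lower for 16 of 20 with 1 higher (16 and 2 adjusted over the list alone; Zfp42 −2.71), glycolysis for 18 of 20 and general pluripotency for 10 of 15. Pou5f1 was at −0.51 (adjusted p = 0.0298), but at 0.01 (0.972) with each array centred on its median. It lost the call without the PGC array of the cultured cells' run (−0.45, 0.0708), without the second PGC array of the other run (−0.47, 0.0872) or without ESC clone 3 (−0.48, 0.05).

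Between PGCs and stem cells 4412 genes differed at least 2-fold, 1183 (26.8%) higher and 3229 lower (limma). Within the runs these were 2960 with 59.1% higher against the single PGC array and 5513 with 23.4% higher against the 3. In both, 1448 were called in the same direction and 141 in opposite ones. Here too both sets of calls share the stem cell arrays and are not independent. Centring each array on its median gave 2606 higher and 1760 lower. By camera 14 lists passed. Those that passed in both runs were gonadal germ cell (adjusted p = 2.48e-12; 1.53e-11 and 3.39e-09 within the runs), piRNA (2.19e-07; 1.53e-05 and 4.26e-06), glycolysis (8.63e-06; 6.48e-08 and 0.000555), naive pluripotency (0.000896; 2.67e-07 and 0.0329) and meiosis (0.00117; 5.23e-07 and 0.0371). Early germ cell (0.000268; 0.0907 and 0.000466) and general pluripotency (0.0322; 0.000642 and 0.176) passed in 1 of the runs. None of the 14 kept its call with an estimated correlation (lowest adjusted p = 0.096, for gonadal germ cell and piRNA).

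Changes from stem cells to PGCLCs and from stem cells to PGCs overlapped. Of the genes changed at least 2-fold, 265 were higher in both PGCLCs and PGCs, 455 lower in both, 57 higher in PGCLCs and lower in PGCs, and 5 the reverse. These counts share the 9 stem cell arrays, which by itself makes changes agree. With separate stem cell arrays for each side, in either of 2 divisions, 208 and 214 were higher in both (49.7 and 64.3 expected if the calls were independent) and 342 and 431 lower in both (99.5 and 119.7 expected). Moving apart were 32 and 65 higher in PGCLCs and lower in PGCs (134 and 182.2 expected) and 6 and 4 the reverse (36.9 and 42.2 expected). Dividing the arrays does not change that stem cells are the reference on both sides. Transcripts particular to stem cells would move the same way in both. The excess over the expected counts therefore does not by itself show a likeness of PGCLCs to PGCs. The correlation of the changes across genes, which are not independent replicates, was 0.442. In simulated arrays of noise alone, where no group differed, sharing the 9 stem cell arrays gave a mean of 0.342. Real changes are not noise alone, so that value does not tell how much of the 0.442 comes from sharing. With separate stem cell arrays the correlation in the data was 0.411 and 0.396. So divided, it was 0.542 and 0.521 with the PGC array of the cultured cells' run and 0.328 and 0.315 with the other 3. Rhox9 (24.5-fold), Itgb3 (3.10) and Prdm1 (2.11) were among the genes higher in PGCLCs, and Dnmt3l (−3.02) and Dnmt3b (−1.87) among those lower, that moved the same way in PGCs. Itgb3 encodes the CD61 used in the sort, so its rise on both sides was selected for. The labels give the sort for PGCs and PGCLCs, except the PGCLCs of iPSC clone 4, and not for stem cells. Effects of the sort shared by both sides were not separated.

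The last comparisons ask whether the origin, iPSC or ESC, leaves a trace. The maternally expressed noncoding RNAs of the imprinted Dlk1-Dio3 region, Meg3, Rian and Mirg, had a list median of −3.16 in iPSCs against ESCs, with Meg3 at 7.14 ± 2.50 (SD, n = 6) against 10.3 ± 0.15 (SD, n = 3). None passed over all genes (limma, adjusted p = 1 each), while 3 of 3 did when adjusted over the list alone. Camera gave adjusted p = 0.00134 for the list, and 0.936 with an estimated correlation. The spread lay between clones: the mean of these RNAs was 4.78 to 5.85 in iPSC clones 1, 3, 5 and 6, 9.79 and 10.07 in clones 2 and 4, and at least 9.89 in the ESC clones. That of clone 2 was 10.21 in its EpiLCs and 7.31 in its PGCLCs, between the 4.47 and 5.31 of clones 3 and 1 and the 8.72 of clone 4. In EpiLCs the differences were −2.63, −2.03 and −2.63 and in PGCLCs −3.73, −2.67 and −2.37, none past the threshold (lowest adjusted p = 0.521). No gene passed between iPSCs and ESCs or between the EpiLCs of the origins (limma, 0 genes each; 579 and 511 at an unadjusted p under 0.05, or 4% and 3.6% of the genes tested). Leaving out ESC clone 3 or iPSC clone 6 gave 2 genes and 1 between iPSCs and ESCs, and leaving out the EpiLCs of ESC clone 3 gave 1 between EpiLCs. Many more passed between EpiLCs with only the arrays compared in the fit or with array weights, as counted with the processing below. The main fit shares its spread with more variable groups. Arrays correlated at 0.988 or above within each EpiLC group and at 0.897 to 0.982 within iPSC-derived PGCLCs. The 0 for EpiLCs thus does not show that the origins are alike.

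**Figure D4:**
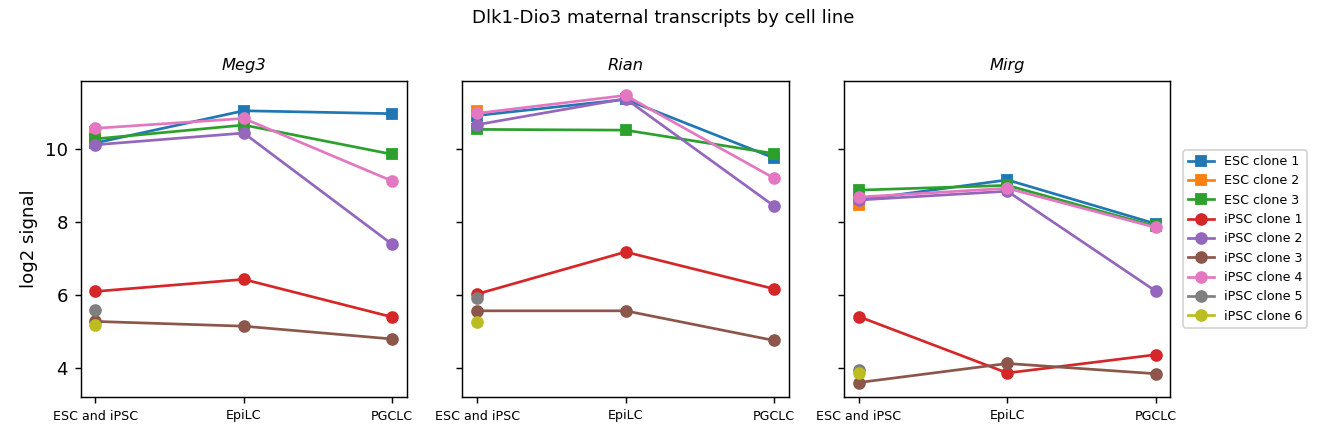
Log2 signal of Meg3, Rian and Mirg in each cell line (colours; squares, ESC clones; circles, iPSC clones), with lines joining the stem cells, EpiLCs and PGCLCs of the same clone. iPSC clones 1 and 3 stay low through all 3 cell types, and clones 5 and 6 were measured as stem cells only.

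In PGCLCs 73 genes were lower from iPSCs than from ESCs by at least 2-fold and 0 higher (limma, 1191 genes at an unadjusted p under 0.05). Among the largest differences were genes of the placental prolactin family and a trophoblast marker. Prl7d1 was at 4.81 ± 1.51 (SD, n = 4) against 9.42 ± 0.38 (SD, n = 2), 24.4-fold lower (adjusted p = 2.6e-05). Tpbpa was 17.9-fold lower (2.41e-06), Prl4a1 15.7-fold, Prl2a1 10.9-fold and Prl6a1 8.73-fold. The trophoblast list as a whole did not differ by the test, with 1 of 13 lower, Tpbpa, and 0 higher (camera, adjusted p = 0.678). Its mean was 8.67 and 7.96 from ESCs and 8.24, 8.12, 8.9 and 7 from iPSCs. With only the PGCLC arrays in the fit no gene passed (0; Tpbpa at adjusted p = 0.347), with each array centred on its median 38 did. Leaving out single PGCLC arrays gave 37 (without iPSC clone 2), 47 (without ESC clone 1), 111 (without iPSC clone 1) and 176 (without iPSC clone 3). Naive pluripotency was lower in iPSC-derived PGCLCs by camera (list median −0.79, adjusted p = 5.79e-06), with 0 of 20 members passing over all genes and 7 when adjusted over the list alone. It lost the call with an estimated correlation (adjusted p = 0.395).

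Whether a step differed between origins was tested directly as an interaction. In the step from EpiLCs to PGCLCs 9 genes rose less, or fell more, from iPSCs. They were the placental genes Tpbpa (−4.39, adjusted p = 0.000399), Prl7d1 (−4.68, 0.00644), Prl4a1 (−3.91, 0.00218), Prl2a1 (−3.30, 0.00805), Prl6a1 (−2.95, 0.0343) and Ctsj (−2.51, 0.000199), and Dnmt3l (−2.91, 0.0117), Phf11d (−2.83, 0.0333) and Enox1 (−1.94, 0.0333). With the cell line as a block 15 passed, 4 of them among the 9 (Ctsj, Tpbpa, Prl4a1 and Enox1), and Prl7d1 (0.0691), Dnmt3l (0.0547), Phf11d (0.0555), Prl2a1 (0.0563) and Prl6a1 (0.119) did not. Leaving out single arrays gave from 2 genes (without the PGCLCs of ESC clone 1) to 24 (without those of ESC clone 3). It gave 5 and 4 without the EpiLCs of ESC clones 1 and 3 and 15 without the PGCLCs of iPSC clone 1. Ctsj and Tpbpa kept their calls without any single array, and the other 7 lost theirs without the PGCLCs of ESC clone 1 (adjusted p from 0.0509 for Prl4a1 to 0.174 for Phf11d), most of them also without other arrays. With only the arrays compared in the fit, or with the stricter filter, which tests fewer genes, 0 genes passed. Ctsj and Tpbpa were thus not called there either. In the step from stem cells to EpiLCs 1 gene passed, the zinc finger gene Zkscan3 (1.39, adjusted p = 0.0359), and with the cell line as a block it did not (0.297, 0 genes). Zkscan3 also lost the call, at adjusted p = 0.0634 to 0.569, without any single array of ESC clones 1, 2 and 3, of iPSC clones 1, 2, 4, 5 and 6, of the EpiLCs of ESC clone 3, or of the EpiLCs of iPSC clones 2, 3 and 4.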

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

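Of the tests below, those on the Dlk1-Dio3 region (cell lines and probe sets), on marker lists in the PGC arrays and on the PGCLC arrays were chosen after the result was seen, and the test of probe position in the PGC arrays and the counts of other splits were not.

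Of the 4 E12.5 PGC arrays, the 1 in the run of the cultured cells differed from the other 3: 41.3% of the genes called against it were higher in PGCLCs, and 80.3% against the other 3. The RNA of the other 3 arrays was read further from the 3′ end, over 3576 genes with probe sets at least 300 bp apart. The difference (other 3 arrays minus the 1) was higher at the upstream probe set by a median of 1.27. Its 95% interval was 1.19 to 1.34, and 76.8% of genes were above 0. Between pairs of PGCLC arrays the medians were −0.3 to 0.12. With each PGCLC array in place of the 1, they were 0.95 to 1.38. The comparison of PGCLCs with PGCs thus carries this difference too. A different labelling of the other 3 could give this pattern. The 3′ minus 5′ signal of the GAPDH control, 1.11 to 1.21 on the other 3 and 1.00 on the 1, did not show it. Somatic RNA on the 1 array was also not excluded, since 6 of 6 marker lists of gonadal, blood and immune cell types had a higher median there than all genes did (0.52). The intervals of 4 of them span that value, those of gonadal somatic cells (median 0.53, −0.22 to 1.73), mesonephros, endothelium and erythroid cells, and those of macrophages (1.77, 1.00 to 3.31) and fibroblasts (3.52, 2.03 to 4.68) lie above it. Genes of tissue dissociation stress were higher there too (2.29) and early germ cell genes were not (−0.33). The other germ cell lists did not follow the early one. Meiosis was at 0.88 (0.44 to 1.51), gonadal germ cell at 0.56 (0.07 to 1.1) and the piRNA pathway at 0.08 (−0.7 to 1.47). All of these intervals span the 0.52 of all genes. A labelling difference could itself move these lists, so both explanations stay open. A difference between the embryos or their sex was not tested.

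Meg3, Rian and Mirg were low in iPSC clones 1 and 3 through 3 cell types and in clones 5 and 6 as stem cells, high in clone 4, and in clone 2 high as stem cells and EpiLCs and intermediate in PGCLCs (7.31). Chance spread between arrays was tested over the 576 pairings of the 4 iPSC lines that were followed. The exact one-sided permutation p was 0.00174, the smallest these allow and the lowest of the 38 lists. Adjusted over the lists it was 0.066, the lowest that a list alone at that p can reach. The adjusted test could therefore not exclude chance for such a list, however strong its pattern, and decides nothing. In stem cells the mean of the 3 genes was 4.78 to 5.85 in iPSC clones 1, 3, 5 and 6, and 9.79 to 10.07 in the other 5. Clones 1 and 3 were at 5.83 and 4.95 as EpiLCs, where the other lines had 10.05 to 10.51. As PGCLCs they were at 5.31 and 4.47, against 7.31 to 9.55. For clones 1 and 3 these values argue against chance spread between arrays. Clones 5 and 6 were measured on 1 array each. A single failing probe set was excluded for Meg3 and Rian, of whose 13 further probe sets 8 followed the mean of the 3 genes (r above 0.8), and stayed open for Mirg, where 0 of 1 did. For Meg3 and Rian, a loss of expression from the maternal copy of the region in iPSC clones 1, 3, 5 and 6 may account for part of the pattern, as a hypothesis found on the same data. It does not by itself predict the paternally expressed neighbour Dlk1, chosen after its values were seen. Dlk1 was also lower in these clones as stem cells (5.19 to 5.68, against 6.49 to 7.72 in the other 5) and as EpiLCs (5.48 and 5.82, against 6.66 to 7.76), but in PGCLCs it was highest in clones 1 and 3 (12.37 and 12.6). DNA methylation at the control region of the domain, or reads told apart by parental allele, would test it. A difference in the parent cells of those clones was not tested.

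PGCLC arrays differed in trophoblast and early germ cell transcripts, with Plac1 from 6.04 to 11.62 and Prdm1 from 6.71 to 11.32. Unsorted cells on the array whose label gives no sort (iPSC clone 4) remained open: its early germ cell mean was the highest of the 6, but the 0.63 over the mean of the others was less than 2 of their SDs (SD 0.37, n = 5). Its trophoblast mean (7) was the lowest and its erythroid mean (6.73) the highest. Other cell types of the embryoid bodies among sorted cells remained open: the trophoblast and early germ cell means had r = −0.742 over the 6 arrays (exact permutation p = 0.0847; rho −0.657, p = 0.175; adjusted p = 0.275 over 6 relations), and r = 0.205 without the 2 farthest arrays, so that any relation rests on those of iPSC clones 3 and 4. Of the other lists, fibroblast (r = −0.693; rho −0.829, p = 0.0583) and neurectoderm (−0.679) went the same way, mesoderm (−0.24) and endothelium (−0.169) weakly so, and endoderm did not (0.0719). The sort for SSEA1 and CD61 would be meant to remove such cells. A difference between lines in how they respond to the induction was not tested.

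Chance as the source of the counts of calls was tested by splitting the arrays of the 2 sides otherwise, in fits of those arrays alone, which changes the real counts. For each comparison of cell types 100 splits were used, the real one and others drawn at random. Chance was excluded to that extent, with only the real split, 1 of 100, reaching the real count. The real count and the highest of the other splits drawn were 1145 and 1 for EpiLCs against stem cells (5005 splits possible) and 1832 and 1 for PGCLCs against EpiLCs (462). They were 1402 and 212 for PGCLCs against stem cells (5005), 3622 and 2550 for PGCLCs against PGCs (210), and 4342 and 3493 for PGCs against stem cells (715). The highest other split of each PGC comparison followed the run, with the PGC array of the cultured cells' run on the side of the cultured cells and 1 array of cultured cells on the side of the other 3, which points to a structure among the PGC arrays. With only the 3 PGC arrays of the other run, the counts were 5514 for PGCLCs against PGCs and 5513 for PGCs against stem cells. These compare arrays of different runs. Among splits that part as many pairs of the same line, the highest others were 489 for EpiLCs against stem cells, 1 for PGCLCs against EpiLCs and 498 for PGCLCs against stem cells. Between iPSCs and ESCs the real split called 0 genes, a count that all 84 splits reach whatever the data (highest other 12), so they test nothing there.

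Single arrays far from the others of their cell type were found in 40 of 323 groups of values (12.4%), where chance gives about 1 in 20. Of these, 10 were on ESC clone 2, with higher signals of Far2 (5.36), Wnt3 (5.36), Fzd2 (9.47), Calcr (6.61) and Lcp1 (6.50), and lower signals of Jam2 (8.74), Morc1 (10.62), Inhbb (6.94), Nanog (12.38) and Gli1 (7.99) than the other 8 stem cell arrays. On the PGC array of the cultured cells' run, 10 differed from the other 3: Klf9 (6.24), Tac2 (6.00), Impact (8.15), Krt8 (10.75), B2m (10.85), Prdm14 (10.53), Upp1 (7.15) and H19 (12.32) were higher, and Tex19.1 (10.02) and Asz1 (5.80) lower. On the EpiLC array from ESC clone 3, 8 were lower: H2-K1 (10.05), Morc1 (5.13), Mylpf (7.73), Esrrb (6.32), Zfp42 (7.69), Sox2 (9.45), Tet2 (6.84) and H19 (6.00). Other EpiLC arrays differed in Mael (9.71, iPSC clone 1, higher) and Afp (3.97, iPSC clone 2, lower). Among PGCLCs, the array from ESC clone 1 was higher in Aire (7.58) and Col3a1 (7.60), that from iPSC clone 3 lower in Spry4 (6.94), that from ESC clone 3 lower in Peg3 (12.04) and that from iPSC clone 4 lower in Meis2 (7.26). Among stem cells, iPSC clone 3 was higher in Ifitm1 (12.94) and Eras (12.45), iPSC clone 5 lower in Ddx4 (7.65) and higher in Dppa4 (12.55), and ESC clone 1 higher in Msx2 (5.54).

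By the test of the difference itself, a step differed between iPSCs and ESCs for Zkscan3 on the way to EpiLCs (1.39 on the log2 scale) and, on the way to PGCLCs, for Ctsj (−2.51), Tpbpa (−4.39), Prl4a1 (−3.91), Prl7d1 (−4.68), Prl2a1 (−3.30), Prl6a1 (−2.95), Dnmt3l (−2.91), Phf11d (−2.83) and Enox1 (−1.94). These calls are insecure: with the cell line as a block Zkscan3, Prl7d1, Prl2a1, Prl6a1, Dnmt3l and Phf11d did not pass, and only Ctsj and Tpbpa passed without any single array. None of the calls on the way to PGCLCs, Ctsj and Tpbpa included, was made with only the arrays compared in the fit or with the stricter filter.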

How the results depend on the processing

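The alternatives that keep only the PGC arrays of 1 run, or leave out the PGCLC arrays from ESC clone 1 and iPSC clone 3, were chosen after the data were seen. The counts between cell types stayed within 1.5 times except without a fold limit, which by construction gave 2524 genes for EpiLCs against stem cells, 3913 for PGCLCs against EpiLCs, 3892 for PGCLCs against stem cells, 7224 for PGCLCs against PGCs and 7913 for PGCs against stem cells, and with only the PGC array of the cultured cells' run (1589 for PGCLCs against PGCs, with fewer arrays). Leaving out single arrays gave 979 to 1233, 1732 to 1891, 1297 to 1615, 3560 to 5514 and 4005 to 5513 in the same order. Comparisons of origin moved more, and apart from the stricter thresholds and smaller sets of arrays the cause was not tested. Between EpiLCs of the origins, 54 genes passed with only the arrays compared in the fit and 148 with array weights. Between PGCLCs of the origins it was 0 with only the arrays compared, 48 with the stricter filter, 38 with each array centred on its median, 317 with array weights, 29 at an adjusted p under 0.01, and 34 without the arrays from ESC clone 1 and iPSC clone 3. The interaction of the step to EpiLCs had 0 genes with the cell line as a block, with only the arrays compared, with the mean or the most variable probe set, with either scaling, with trended and robust moderation, at the stricter threshold and with only the clones that gave EpiLCs and PGCLCs, and 66 with array weights. The interaction of the step to PGCLCs had 15 with the cell line as a block, 0 with only the arrays compared or with the stricter filter, 186 with array weights, 5 at the stricter threshold and 4 without the arrays from ESC clone 1 and iPSC clone 3. Leaving out single arrays gave 0 to 2 genes between iPSCs and ESCs (2 without ESC clone 3, 1 without iPSC clone 6), 0 to 1 between EpiLCs (1 without the EpiLCs of ESC clone 3), 37 to 176 between PGCLCs (without those of iPSC clones 2 and 3), 0 to 1 for the step to EpiLCs and 2 to 24 for the step to PGCLCs (without the PGCLCs of ESC clones 1 and 3). Among the values of named genes, the cell line as a block changed no call but those given in the results and those of Dppa3 (−1.14, adjusted p = 0.0777) and Kit (−0.96, 0.053), lost in EpiLCs against stem cells, and of Pou3f1 (1.13, 0.0167), gained there. Of all list members that the rule takes, most of them not named here, it ended 15 of 263 calls. Of 255 values of named genes 223 passed, and 185 of these kept sign and call under every alternative applied to them. The alternative thresholds were not applied to single genes, nor was a setting whose filter left the gene out. Otx2, Dppa3 and Kit in EpiLCs against stem cells were the least secure, with calls lost without many single arrays, such as the EpiLCs of ESC clone 3 (adjusted p = 0.095, 0.107 and 0.0747). Of these values, the sign turned for Slc2a3 in PGCLCs against PGCs (2.27, and −1.96 on its most variable probe set), for Jun in the same comparison (2.41, and −1.51 with the PGC array of the cultured cells' run) and for Pou5f1 in PGCs against stem cells (−0.51, and 0.01 with arrays centred). Among all list members that the rule takes, it turned with the PGC array of the cultured cells' run for 20 of 113 in PGCLCs against PGCs and 13 of 115 in PGCs against stem cells. Of the list tests, dissociation stress turned in PGCLCs against PGCs (adjusted p = 0.0196, lower, with that PGC array alone), and by fry, which does not set a list against other genes, histone methylation (adjusted p = 0.028), maternally expressed imprinted genes (0.022) and X inactivation genes (0.0193) were higher there and FGF targets (0.00712) lower in PGCs against stem cells, against camera's direction. With an estimated correlation 66 of 76 calls of lists were lost, with the cell line as a block 4. Splitting the stem cell arrays between the comparisons left 208 and 214 genes higher in both PGCLCs and PGCs, and 342 and 431 lower in both. Near the background of the array, folds against a dim group (such as Fgf4 in PGCs or Fgf5 in PGCLCs) depend on where the signal levels off and are limited by it.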

Other observations

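Of the 22 measured genes of oxidative phosphorylation, few passed between the cultured cells (limma): 2 were lower in EpiLCs than in stem cells (0 adjusted over the list alone), from EpiLCs to PGCLCs 1 rose and 1 fell (0 and 1), and 3 were lower in PGCLCs than in stem cells (2) and none higher. Antigen presentation genes had a list mean of 8.29 ± 0.12 (SD, n = 6) in EpiLCs, 7.74 ± 0.26 (SD, n = 9) in stem cells, 7.74 ± 0.50 (SD, n = 6) in PGCLCs and 6.27 ± 0.53 (SD, n = 4) in PGCs. In EpiLCs against stem cells 4 of 10 rose and none fell, H2-K1 among them at 1.61 (adjusted p = 0.02), without the list passing by camera (adjusted p = 0.0871), and H2-K1 lost its call with only the stem cell clones that gave EpiLCs and PGCLCs (1.54, 0.0533). Genes of DNA demethylation fell for 3 of 12 in EpiLCs, with Tet2 the largest, and the list did not pass by camera (adjusted p = 0.0984).

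On the PGCLC arrays, the placental prolactin gene Prl7d1 and Plac1, another placental gene, were not highest on the same arrays. Prl7d1 was at 9.68 and 9.15 in the PGCLCs of ESC clones 1 and 3, at 6.86 in those of iPSC clone 1, and at 3.47, 3.91 and 4.99 in those of iPSC clones 2, 3 and 4, against 3.19 to 3.37 in stem cells. Plac1 was highest in iPSC clone 3 (11.62) and next in ESC clone 1 (10.44). Erythroid genes had a list mean of 6.53 and 6.73 in the PGCLCs of ESC clone 3 and iPSC clone 4, and of 4.68 to 5.53 in the other 4.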
